A study of Mus musculus with 6 samples.

How the data were processed

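RNA from splenic CD3+ T cells of mice was sequenced in 6 libraries, 3 from allogeneic and 3 from syngeneic stem cell recipients. Per the labels' protocols, spleens were made into cell suspensions, T cells were taken with an isolation kit, ribosomal RNA was depleted and libraries were built with a kit from New England Biolabs. The submitters' processing notes name limma, without its role. The aligner, the counting tool, the genome build and the strand setting are not given in the sources used here.

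The deposited table gives 1 expression value per gene and library and its header does not name the unit. The unit was read from the values: multiplied by an annotated transcript length, the values of a library were whole multiples of a fixed step that corresponds to a whole-number library total, as FPKM gives and TPM does not. The deposited values are therefore treated as FPKM that the authors computed by dividing reads by gene length and library total. Whether single reads or read pairs were counted is not stated, and "reads" stands for either. The library totals were found from 1036 genes with a single annotated transcript (GENCODE M21), and with them all values of 8468 of 8468 genes (100.0%) came out as whole reads, at most 2.6e-05 from a whole number. In simulated reads with known lengths, 495 of 500 gene lengths came back exactly and 5 up to a common factor, so a recovered length can be too short for a few genes. A gene had a median of 165.0 reads per library.

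The table holds a part of the genes. Its genes account for 42.15% to 45.50% of the reads of each library. Among 4825 genes averaging over 100 reads per library, none had a log2 ratio of mean allo-HSCT to mean syn-HSCT FPKM between -0.37 and 0.21, so the table appears to be limited to genes that differed between the groups. Counts of changed genes and adjusted p-values describe this table and not the transcriptome, and gene lists were compared with the other genes of this table. A gene or list member outside it is not analysed here. Of the symbols, 8419 were found in the RefSeq gene table (GRCm38.p6) and 8164 in GENCODE M21. Because the authors' build is not given, no coordinates are printed.

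Genes with at least 1 FPKM in 3 or more libraries (5460) were tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with a mean-variance trend, all 6 libraries and no covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and genes with an absolute log2 fold change of at least 1 were counted as well. A log2 fold change on this scale understates the change of low genes, and the folds printed are ratios of mean FPKM. On simulated counts for these genes at the real library totals, with a dispersion of 0.01 and 5349 genes tested, the same test recovered 77.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold, and called 9 of 5155 unchanged genes. Most simulated genes were unchanged, and every simulated library had the same dispersion. In the real table most tested genes passed the threshold, which makes the adjustment more lenient, and the spread differed between libraries. The simulation therefore does not show how often unchanged genes are called in these data. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so single genes were tested by limma only.

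Before the data were examined, 33 gene lists were fixed for T cell programmes, other cell types, RNA handling, donor strain and sex. Many lists are incomplete in this table. It holds 9 of 15 fixed members for inhibitory receptors and exhaustion, 14 of 27 for cell cycle, 14 of 29 for oxidative phosphorylation and 8 of 17 for glycolysis. Members outside it may be unchanged, so a count over tested members does not describe the whole list. The 29 lists with at least 3 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move one way and does not compare them with other genes, were run beside it. In a simulation, a list moved 1.5-fold was found (adjusted p = 5.3e-22) and 0 of the unmoved lists were called. Its genes were drawn independently and most were unchanged. In the real table most tested genes passed the threshold, and the estimated correlation reached 0.66 in the macrophage and monocyte list. The simulation therefore cannot show how often camera calls unmoved lists in these data. Named genes followed a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls past the threshold with groups that do not overlap and a mean at or above the median of tested genes (8.96 FPKM), without receptor segments, unnamed genes, pseudogenes and haemoglobins. It adds up to 3 members past the threshold with the largest change from each list, or the 1 with the highest mean where none passes, and every measured member of the strain and sex lists. Other genes named, such as the few members that went against their list or Cd3e, were chosen after their values were seen. A gene that the rule selects is not reported here.

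Alternatives were other scalings (sample medians set equal, with and without dominating genes, and quantile normalization), no trend, no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 5, the replicate number as a block, sample quality weights and each library left out. Added after the data were seen were limma-voom on the recovered reads (genes with 10 or more reads in 3 or more libraries), a shift to the middle of the range of fold changes missing from the table (-0.08), and removal of a smooth trend with gene length from each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Libraries of a group were compared pair by pair, and each pair differed by more than read sampling (chi-square over degrees of freedom 2.73 to 25.5). All 6 were counted as separate samples, but that difference does not show that they came from separate animals.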

Results

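The series measured RNA of CD3+ T cells from the spleen after haematopoietic stem cell transplantation (HSCT), in which a host receives blood-forming cells of a donor. All hosts were Balb/c mice. The syn-HSCT group received Balb/c cells and the allo-HSCT group received C57BL/6 cells, a donor strain with other transplantation antigens, which is the setting of graft-versus-host disease. Each group had 3 libraries. The totals recovered from the FPKM values were 16462425, 17524496 and 15642385 reads for syn-HSCT replicates 1 to 3 and 16909547, 17143498 and 16330845 reads for allo-HSCT replicates 1 to 3. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

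The comparison asks how splenic T cells of allogeneic recipients differ in gene expression from those of syngeneic recipients. Among tested list members, all 17 T cell receptor and lineage genes and all 9 inhibitory receptor and exhaustion genes rose in allo-HSCT. So did 16 of 21 cytotoxic, 11 of 13 Th1 and 22 of 23 interferon gamma response genes. By contrast, 11 of 13 macrophage and monocyte genes, 8 of 9 Th17 genes and all 12 immediate early and heat shock genes fell. Camera called these 8 lists at its preset correlation and none of them with an estimated correlation (adjusted p = 0.14 to 0.46). Over all lists 313 of 323 tested members passed the threshold in either direction, as did 5118 of all 5460 tested genes. The table holds 9 of the 15 fixed members of the inhibitory receptor and exhaustion list. Gzmb, the cytotoxic protease granzyme B, stood at 48.5 ± 0.845 FPKM (SD, n = 3) in syn-HSCT and at 377 ± 51.1 (n = 3) in allo-HSCT, 7.77-fold higher (log2 fold change 2.92, SE 0.0984, limma adjusted p = 2.25e-08). Pdcd1, which encodes the inhibitory receptor PD-1, rose 5.54-fold from 10.9 ± 0.769 to 60.4 ± 2.91 FPKM (log2 fold change 2.37, SE 0.0785, limma adjusted p = 2.21e-08). Cxcl2, a chemokine that attracts neutrophils, was 13.7-fold lower, at 322 ± 13.0 FPKM in syn-HSCT and 23.5 ± 1.36 in allo-HSCT (log2 fold change -3.72, SE 0.076, limma adjusted p = 1.65e-09).

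Among well-expressed genes, with the unnamed genes and other classes that the naming rule leaves out set aside, the 8 largest rises were those of Chil3, Ly6a, Rpl21, Gzmb, Rps2, Pdcd1, H2-Q7 and Klrc1. Gm42226, left out as unnamed, went from 0.0507 to 32.4 FPKM. Chil3, a secreted chitinase-like protein of myeloid cells, rose 11.99-fold from 29.9 ± 3.64 to 359 ± 75.4 FPKM. Ly6a, the surface protein Sca-1 whose level is known to differ between mouse strains, rose 11.7-fold from 19.0 ± 2.34 to 222 ± 45.7 FPKM. Klrc1, which encodes the lectin-like receptor NKG2A, rose 5.71-fold to 28.2 ± 7.03 FPKM. Rpl21 (9.01-fold), Rps2 (6.71-fold) and H2-Q7 (5.66-fold) are uncertain, because ribosomal protein genes have processed pseudogenes and H2-Q genes have close paralogs among which reads can be split. By the same rule, the 8 largest falls were those of Cxcl2, F13a1, Cxcl1, Cd14, Lyz2, Tlr2, Ccl9 and Prtn3. Lyz2, the lysozyme of macrophages and granulocytes, was 7.51-fold lower, at 1634 ± 254 FPKM in syn-HSCT and 217 ± 44.5 in allo-HSCT. F13a1 was 10.4-fold, Cxcl1 12.5-fold, Cd14 8.55-fold, Tlr2 8.13-fold, Ccl9 7.75-fold and Prtn3 6.54-fold lower.

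Of 5460 genes tested, limma called 5118 at adjusted p under 0.05, with 2618 higher and 2500 lower in allo-HSCT. With an absolute log2 fold change of at least 1 there were 204 higher and 432 lower. The groups did not overlap in 4968 genes (91%), where chance gives 10%. The deposited table holds almost no genes with small changes, so these counts describe genes already chosen by their difference, and donor strain changed together with the type of transplant in every sample.

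All 17 genes of the T cell receptor complex and lineage rose (median log2 fold change 0.79). Camera gave an adjusted p of 7.8e-05 for the list, and adjusted p = 0.18 with an estimated correlation. The coreceptor genes Cd8a (3.15-fold, from 29.2 ± 1.08 to 91.8 ± 2.49 FPKM) and Cd8b1 (2.90-fold) rose more than Cd247, the CD3 zeta chain (2.10-fold). Genes of other cell types moved with the groups as well, in both directions, as the macrophage and granulocyte lists described further on show. Each value is of a whole isolate, so it does not show which cells carried a change, also for members of the T cell lists. All 12 tested genes of naive and central memory T cells rose, among them Actn1 (1.99-fold), Tcf7, a transcription factor of naive and memory cells (1.88-fold), and Il6ra (1.74-fold). The camera adjusted p was 0.0038 for this list, and adjusted p = 0.36 with an estimated correlation.

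**Figure D1:**
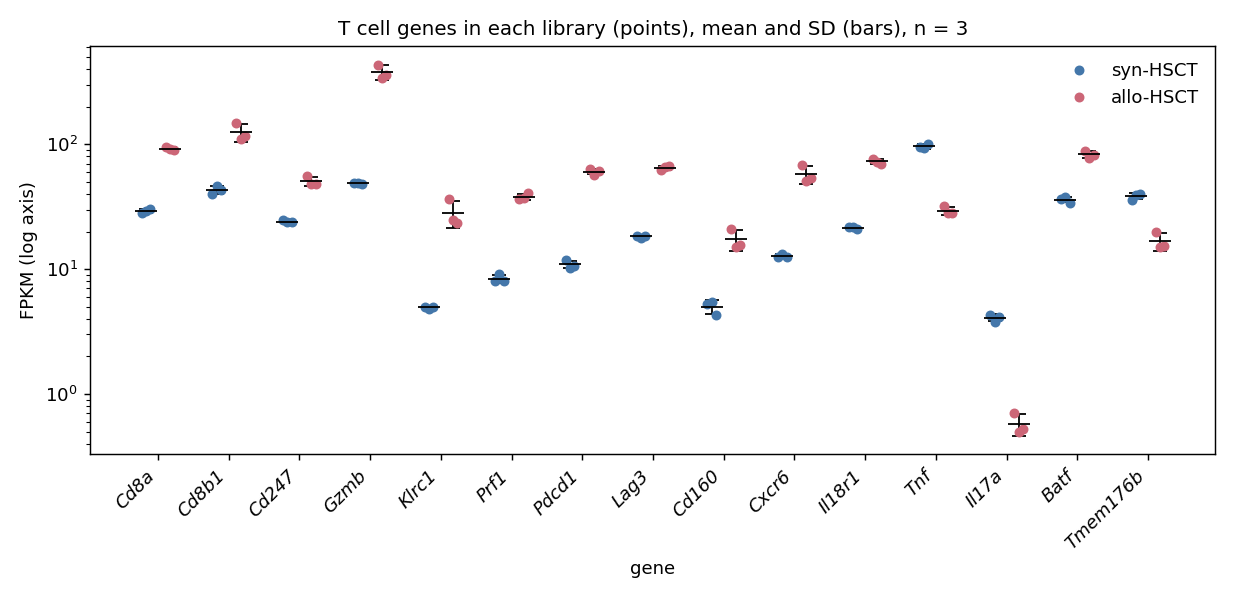
FPKM on a log axis of T cell genes in each of the 3 syn-HSCT and 3 allo-HSCT libraries (points), with the mean and SD of each group (bars). The groups do not overlap in any gene shown, and Gzmb lies at a mean of 48.5 in syn-HSCT and 377 in allo-HSCT while Il17a lies at 4.09 and 0.576.

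Of 21 cytotoxic effector genes, 16 rose and 5 fell (camera adjusted p = 0.015, or adjusted p = 0.43 with an estimated correlation), a call that did not hold at a mean of at least 5 FPKM (adjusted p = 0.051). Prf1, which encodes the pore-forming protein perforin, rose 4.52-fold from 8.39 ± 0.585 to 37.9 ± 2.14 FPKM. The 5 that fell, named after their values were seen, were Klrg1 and Zeb2, which mark terminal effector cells, the transcription factor gene Eomes, and the chemokines Ccl3 and Ccl4. All 9 tested inhibitory receptor and exhaustion genes rose, with a median log2 fold change of 1.13 (camera adjusted p = 5.3e-04, or adjusted p = 0.14 with an estimated correlation). Lag3 rose 3.54-fold from 18.3 ± 0.422 to 64.7 ± 2.65 FPKM and Cd160 rose 3.46-fold. Allo-HSCT replicate 1 stood apart from the other 2 allo-HSCT libraries. Its log2 values lay above theirs by a median of 0.32 in the cytotoxic list and 0.25 in the follicular helper list, and below theirs by a median of -0.32 in the naive and central memory list. Without it the member counts of these lists did not change.

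Among T helper lists, 11 of 13 Th1 genes rose, led by the chemokine receptor Cxcr6 (4.49-fold) and the interleukin-18 receptor Il18r1 (3.40-fold), while Hlx fell and Tnf was 3.27-fold lower, at 96.0 ± 3.91 and 29.4 ± 2.13 FPKM. The camera adjusted p was 0.0038, and adjusted p = 0.35 with an estimated correlation. Of 9 Th17 genes, 8 fell and 1 rose (camera adjusted p = 0.044, or adjusted p = 0.43 with an estimated correlation). Il17a, the cytokine that names these cells, was 7.09-fold lower, at 4.09 ± 0.258 and 0.576 ± 0.114 FPKM, and rested on 237 reads over the 3 syn-HSCT libraries. Tmem176b fell 2.30-fold and Batf, a transcription factor also active in other T cells, rose 2.29-fold. The Th17 call did not hold without syn-HSCT replicate 3 or without allo-HSCT replicate 3 (camera adjusted p = 0.052 in both), with quantile normalization (0.053), with the gene length trend removed (0.055) or at a mean of at least 5 FPKM (0.73). Of 9 follicular helper genes, 8 rose and Bcl6 fell (camera adjusted p = 0.012, or adjusted p = 0.35 with an estimated correlation and 0.051 at a mean of at least 5 FPKM). Il21 rose 11.98-fold from a low 0.411 ± 0.061 to 4.92 ± 0.835 FPKM, Sostdc1 rose 5.36-fold and Slamf6 2.07-fold. The Th2 and regulatory T cell lists did not pass camera (adjusted p = 0.66 and 0.32). Among Th2 genes 2 rose and 3 fell of 6, with Areg 2.02-fold, Ccr4 1.83-fold and Ccr8 1.53-fold lower. Among regulatory T cell genes 7 rose and 3 fell of 10, with Il10 1.95-fold lower, Il2ra 1.75-fold higher and Itgae 1.67-fold higher.

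Of 23 interferon gamma response genes, 22 rose and Irf8 fell (camera adjusted p = 1.9e-04, or adjusted p = 0.14 with an estimated correlation). The chemokine Cxcl9 rose 3.85-fold from 2.38 ± 0.511 to 9.15 ± 1.64 FPKM, and the guanylate-binding proteins Gbp6 and Gbp2 rose 2.20-fold and 2.09-fold. The type I interferon list was divided, with 9 genes higher and 5 lower of 14, and Oasl1 (2.22-fold), Ifi44 (1.88-fold) and Bst2 (1.79-fold) lower. Its median log2 fold change was 0.26, its mean was -0.03 and fry put it lower where camera put it higher, neither past the threshold (adjusted p = 0.58 and 0.64). All 12 tested genes of the MHC region rose (camera adjusted p = 5.3e-04, or adjusted p = 0.14 with an estimated correlation), with the class II genes H2-Eb1 2.04-fold and H2-Ab1 2.002-fold higher. The donors carry different MHC haplotypes, so the values of these genes also depend on how well reads of each haplotype matched the authors' reference. Of the strain list, Ly6a rose and Nnt, which carries a known deletion in C57BL/6J mice, was 1.74-fold lower, at 17.4 ± 0.309 and 10.01 ± 0.737 FPKM.

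Of 12 costimulation and activation genes, 10 rose and 2 (Cd44 and Nr4a1) fell, with Cd226 2.24-fold, Cd40lg 1.92-fold and Nfatc1 1.72-fold higher (camera adjusted p = 0.042, or adjusted p = 0.35 with an estimated correlation). That call did not hold without allo-HSCT replicate 1 (adjusted p = 0.057), with quantile normalization (0.054), at a mean of at least 5 FPKM (0.055) or with sample quality weights (0.064). Of 16 cytokine receptor and STAT genes, 15 rose, among them Il12rb1 (2.13-fold), Stat4 (1.79-fold) and Il2rb (1.74-fold), and Il10ra fell (camera adjusted p = 0.0029, or adjusted p = 0.35 with an estimated correlation). Homing receptors were divided, with 9 higher and 5 lower of 15 (camera adjusted p = 0.15, and 0.015 at a mean of at least 5 FPKM). In that list Cxcr3 was 2.86-fold higher and Ccr2, a receptor of monocytes and some T cells, 3.25-fold lower.

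All 14 tested cell cycle genes fell (median log2 fold change -0.52), among them Bub1 (1.78-fold), Cdk1 (1.70-fold) and Stmn1 (1.59-fold), with a camera adjusted p of 0.0023 and adjusted p = 0.35 with an estimated correlation. Genes of granulocyte precursors, Mpo (5.82-fold) and Prtn3 (6.54-fold), and the progenitor and mast cell gene Kit (2.95-fold) fell as well, and 11 of 13 macrophage and monocyte genes fell. All 14 tested oxidative phosphorylation genes also fell, with Ndufa4 1.78-fold, Cycs 1.63-fold and Cox6c 1.58-fold lower (camera adjusted p = 0.0038, or adjusted p = 0.43 with an estimated correlation). Fold changes across genes rose with gene length (Spearman rho 0.24 over 5460 genes, which are not independent replicates), and allo-HSCT replicate 1 lay above the other 2 allo-HSCT libraries by a median of 0.29 in this list. With a smooth length trend removed from each library, 6 of the 14 still fell and the list no longer passed (camera adjusted p = 0.2). Of 8 glycolysis genes 7 rose and Hk2 was 1.91-fold lower, with Hif1a 1.82-fold and Slc2a3 1.54-fold higher (camera adjusted p = 0.071). Without allo-HSCT replicate 1 this list passed (adjusted p = 0.048), as it did with no filter (0.03). Apoptosis genes were divided, with 8 higher and 5 lower of 13 (camera adjusted p = 0.66), Fasl 2.04-fold and Bcl2a1b 1.92-fold higher, and Pmaip1 1.91-fold lower.

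**Figure D2:**
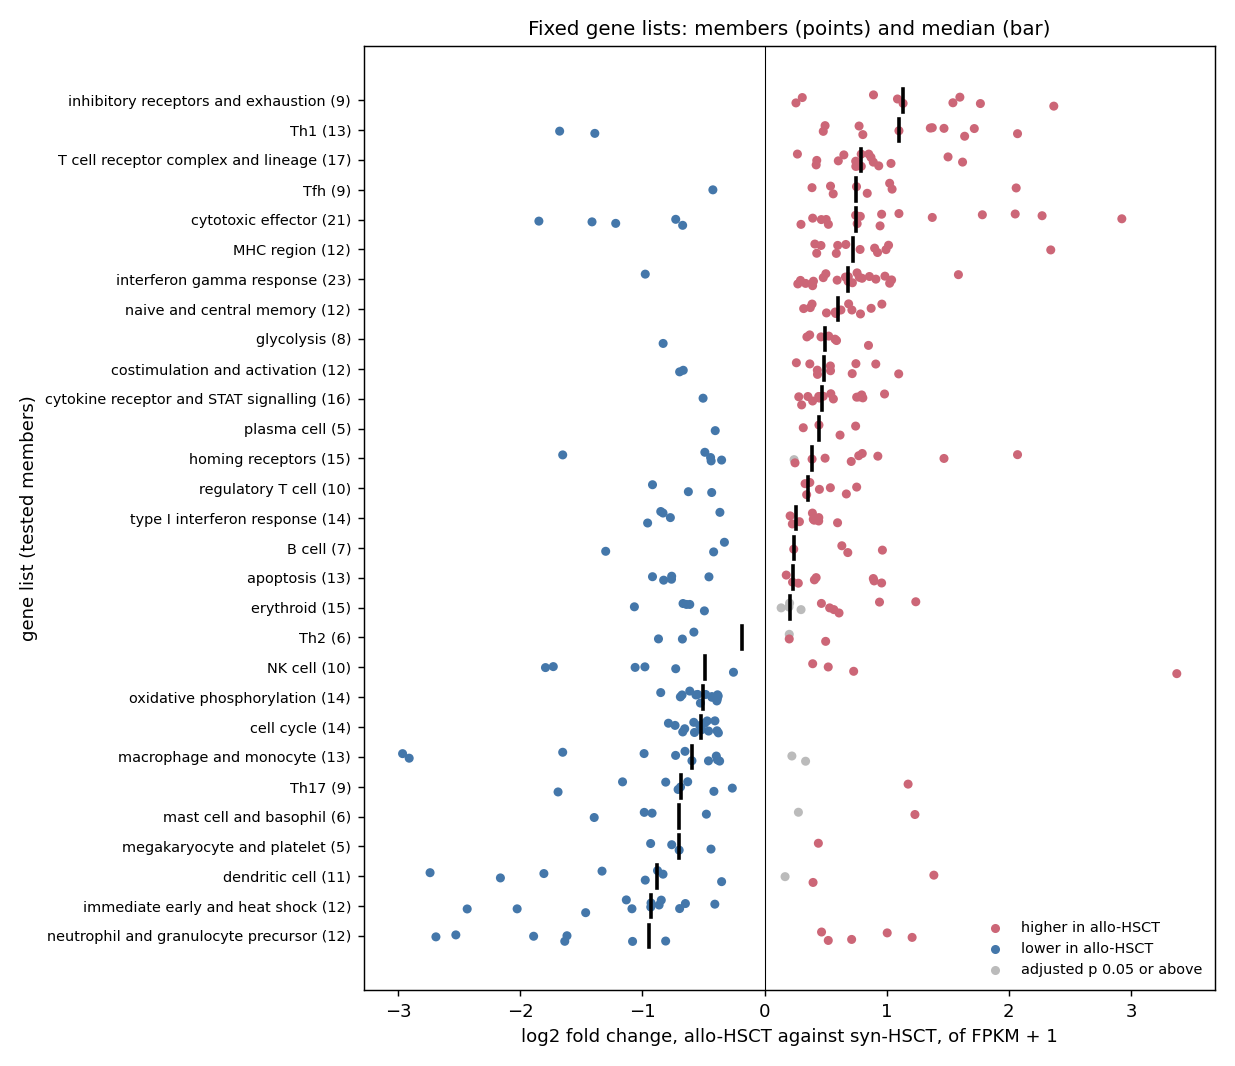
Log2 fold change of FPKM + 1, allo-HSCT against syn-HSCT, of each tested member (points) of the 29 fixed gene lists, with the list median (black bars) and the number of tested members in parentheses. All 17 T cell receptor and lineage genes lie above 0 and all 12 immediate early and heat shock genes below 0, while lists such as neutrophil and granulocyte precursor (median -0.95) hold members on both sides.

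Genes of other cell types were present in both groups. Of 13 macrophage and monocyte genes 11 fell and none rose past the threshold (camera adjusted p = 0.0076, or adjusted p = 0.46 with an estimated correlation), and allo-HSCT replicate 1 lay above the other 2 allo-HSCT libraries by a median of 0.35 in this list. Cd14, a receptor of monocytes, stood at 74.9 ± 2.19 FPKM in syn-HSCT and 8.75 ± 0.994 in allo-HSCT, next to the T cell gene Cd3e at 98.5 ± 0.815 and 182 ± 20.5. The neutrophil and granulocyte precursor list did not pass camera (adjusted p = 0.29), with 7 genes lower and 5 higher of 12. Mpo (5.82-fold), Prtn3 and Ctsg (3.71-fold), proteases and an oxidase of the primary granules made by precursors, were lower. The 5 higher genes, named after their values were seen, were Lcn2, Ltf, Ngp, Mmp9 and Retnlg, which are made at later stages of granulocyte maturation. Lcn2 rose 2.35-fold from 60.7 ± 1.07 to 143 ± 24.1 FPKM. Of 11 dendritic cell genes 8 fell and 2 (Xcr1 and Batf3) rose (camera adjusted p = 0.03, or adjusted p = 0.35 with an estimated correlation). Siglech, a marker of plasmacytoid dendritic cells, was 22.9-fold lower, at 7.99 ± 0.320 and 0.350 ± 0.118 FPKM, and Clec10a (7.82-fold) and Cd209a (12.4-fold) were lower too.

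The remaining lists of other cell types were divided or small. Of 10 NK cell genes 4 rose and 6 fell (camera adjusted p = 0.56), with Klrb1b 46.6-fold higher on 29 reads over the 3 syn-HSCT libraries, and Ncr1 3.58-fold and Tyrobp 3.44-fold lower. Klrb1b belongs to a receptor family that varies between mouse strains. Of 7 B cell genes 4 rose and 3 fell (adjusted p = 0.63), with Cd22 2.55-fold and Pou2af1 1.72-fold higher and Spib 4.57-fold lower. Of 5 plasma cell genes 4 rose and Xbp1 fell (adjusted p = 0.27), with Prdm1 1.94-fold, Jchain 1.56-fold and Mzb1 1.40-fold higher. Erythroid genes were divided, with 6 higher and 5 lower of 15 (adjusted p = 0.50), or 9 and 5 with sample medians set equal, with quantile normalization or with a shift to the middle of the missing range, and 10 and 5 with the length trend removed. Allo-HSCT replicate 1 lay above the other 2 allo-HSCT libraries by a median of 0.25 in this list, 0.37 in the NK cell list and 0.31 in the mast cell and basophil list. Of the haemoglobin genes, 3 of 4, which are near-identical copies in pairs, rose, Hbb-bs from 138 ± 16.1 to 200.1 ± 28.2 FPKM. Camera did not call these genes (adjusted p = 0.11 over 7 gene families, or adjusted p = 0.48 with an estimated correlation). Their median log2 fold change was 0.55, and allo-HSCT replicate 1 lay above the other 2 allo-HSCT libraries by a median of 0.312. Slc4a1 (3.97-fold) and Alas2 (2.30-fold) were higher and Klf1 2.70-fold lower. In the megakaryocyte list 4 of 5 genes fell and Itgb3 rose (adjusted p = 0.29), among them Treml1 (2.10-fold) and Pf4 (1.66-fold). In the mast cell and basophil list 4 of 6 fell and 1 rose (adjusted p = 0.32), with Kit 2.95-fold and Gata2 2.11-fold lower and Fcer1a 2.53-fold higher. Both tested stroma and endothelium genes, Pdgfrb and Stab2, were lower (2.09-fold and 1.40-fold).

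**Figure D3:**
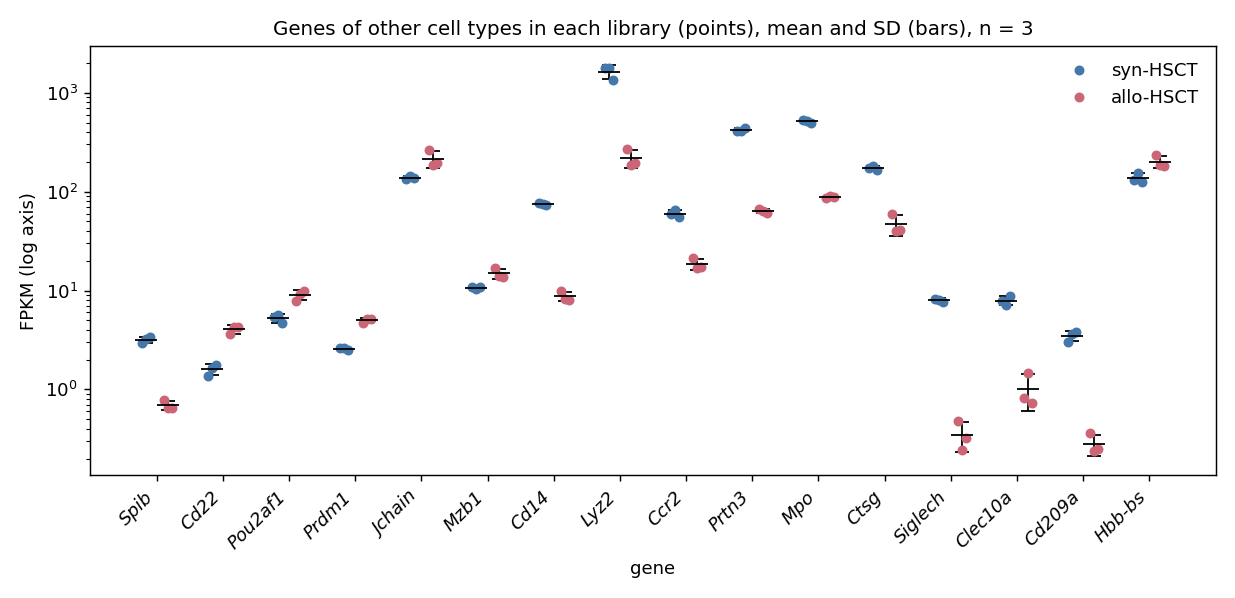
FPKM on a log axis of genes of B cells, plasma cells, macrophages, granulocyte precursors, dendritic cells and red cells in each of the 3 syn-HSCT and 3 allo-HSCT libraries (points), with the mean and SD of each group (bars). Lyz2 lies at a mean of 1634 in syn-HSCT and 217 in allo-HSCT, while Jchain lies at 139 and 216.

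All 12 tested immediate early and heat shock genes, which respond to cell handling as well as to activation, were lower in allo-HSCT (camera adjusted p = 2.4e-04, or adjusted p = 0.35 with an estimated correlation). Macrophage and monocyte genes fell in the same isolates, and the values do not show which cells carried the fall of these 12 genes. Atf3 was 5.56-fold lower, at 148 ± 0.944 and 26.6 ± 2.35 FPKM, Ier3 4.19-fold and Hspa1a 2.88-fold lower. Allo-HSCT replicate 1 lay below the other 2 allo-HSCT libraries by a median of -0.23 in this list. Camera with the preset correlation called 16 of 29 lists, 10 higher and 6 lower, and 0 with an estimated correlation (4 lists at an unadjusted p under 0.05), while fry, which compares no list with other genes, called 25. Adjusted over the list alone, member counts were the same in 28 lists as over all genes tested, and homing receptors gained 1 (10 higher). Without allo-HSCT replicate 1 the member counts were the same in 25 of the 29 lists.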

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

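Limma-voom on recovered reads, the shift to the middle of the missing range and the removal of the length trend were chosen after the data were seen. The count of changed genes stayed within 1.5 times of 5118 under every alternative run, from 3487 at a mean of at least 5 FPKM, where 3595 genes were tested, to 6175 with no filter, and 4353 with the length trend removed (4217 shared calls). The table appears limited to genes that differed, and 5118 of 5460 tested genes passed in the main fit, so a stable count was likely beforehand. Leaving out a library gave 4657 to 5190 genes. The 636 genes with an absolute log2 fold change of at least 1 became 991 with a pseudocount of 0.1 and 243 with 5, since the pseudocount shrinks folds of low genes, 394 at a mean of at least 5 FPKM and 1621 with voom, whose offset is far smaller and which tests 6886 genes. Leaving out a library gave 624 to 667. Camera called 16 lists, 15 to 16 with a library left out, 13 at a mean of at least 5 FPKM, 14 with quantile normalization or the length trend removed, 17 with no filter, 25 with fry in its place and 0 with an estimated correlation. Of 97 named genes, 1825 of 1826 values under the alternatives kept direction and side of the threshold, and Pf4 with the length trend removed was the exception. That count holds both changes of the filter, which were added for single genes after the data were seen, and 17 of these genes have no value at a mean of at least 5 FPKM. The naming rule picks genes past the threshold with the largest changes, so this stability was likely beforehand as well. Of 550 list values, none passed the threshold in the opposite direction, 28 lost and 12 gained a call. The type I interferon list changed direction with fry, without passing (adjusted p = 0.58). Same-numbered libraries did not deviate together (r = -0.02, -0.20 and 0.08, and not each library was closest to its own number). With 3 libraries per group this cannot show whether equal numbers mark a shared batch. The replicate block gave 5105 genes (636 with the larger change) and 16 lists. The 3008 genes below the filter were not tested in the main comparison.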

Other observations

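The tests of the T cell pattern, of the length trend as the whole cause and of the splits of the samples were chosen after the results they measure had been seen. The tests of the genes near 0 in a group, of the length trend and of other cells in allo-HSCT replicate 1 were set before. Gene families picked by symbol after the values were seen showed further groups. All 8 Gimap genes, small GTPases of lymphocytes, rose (median log2 fold change 0.65, camera adjusted p = 0.0028 over 7 families, or adjusted p = 0.34 with an estimated correlation), with Gimap3 1.68-fold higher. Of 134 Zfp zinc finger genes, 96 rose and 25 fell (camera adjusted p = 0.0015, or adjusted p = 0.095 with an estimated correlation), and 70 rose and 24 fell with the gene length trend removed. Of 25 mitochondrial ribosomal protein genes, 23 fell (camera adjusted p = 0.0025, or adjusted p = 0.48 with an estimated correlation), and 11 fell with that trend removed. Of 24 Nduf genes of respiratory complex I, 23 fell and 9 still did with that trend removed. Cytoplasmic ribosomal proteins went both ways, 10 higher and 7 lower of 18 (11 and 2 with that trend removed), with Rpl29 4.67-fold, Rpl26 3.40-fold and Rps18 2.90-fold higher, values that are uncertain because of processed pseudogenes. Allo-HSCT replicate 1 lay above the other 2 allo-HSCT libraries by a median of 0.466 in the cytoplasmic ribosomal genes, more than that family's median log2 fold change of 0.363, by 0.406 in the Nduf genes and by 0.295 in the mitochondrial ribosomal genes. Genes with Gm or Rik symbols were divided, 54 higher and 54 lower of 124, or 58 and 32 with that trend removed.

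T cell receptor genes were higher in allo-HSCT. The other scalings tried did not remove this rise, since the list's median log2 fold change was 0.84 at its lowest under them. They shifted the median gene by only 0.05 to 0.08 log2 units, within a table that appears limited to genes that differed. A larger scaling error was therefore not tested. A lower share of T cells in the syn-HSCT isolates stays open. Log2 fold changes were not shown to differ between the 9 lists of other cell types (permutation over 77 unshared genes, p = 0.28, with genes not independent), while 25 of the 77 rose and 44 fell. That test cannot decide the question, because a lower share of T cells could come with more cells of only some other types. The lists would then differ. Every library was then centred on the T cell receptor and lineage genes, which took out 0.819 log2 units. Of the 25 genes of the cytotoxic list and the inhibitory receptor and exhaustion list that had risen, 12 were still higher, Gzmb by 2.11 and Pdcd1 by 1.55 log2 units. These 12 rose by more than the mean of the centring genes, so a rise by that mean alone does not account for them. The centring genes did not rise equally, since 3 of the 17 were higher and 4 lower after it. Before centring, the coreceptor genes Cd8a and Cd8b1 rose by 1.621 and 1.502 log2 units. Of the 12, Gzmb, Prf1, Klrc1, Serpinb9, Pdcd1 and Lag3 rose more than Cd8a, by 1.77 (Lag3) to 2.92 (Gzmb). Ifng, Tbx21, Havcr2, Tigit, Cd160 and Tox rose less, so centring cannot tell their rise from that of the coreceptor genes. Over the whole lists the cytotoxic genes were divided with that centring (6 higher and 10 lower of 21, median -0.07, against 16 and 5 before). Of 9 inhibitory receptor and exhaustion genes, 6 were higher and 2 lower. Of the other 13 of the 25 genes, 7 lay below the common rise, such as Gzma by -0.425 and Cd38 by -0.562 log2 units. The other 6, such as Nkg7 and Ccl5, were neither higher nor lower past the threshold. They are too few to decide whether a common rise is part of their change. A larger effector response of allogeneic T cells, more granulocyte precursors and monocytes in the syn-HSCT isolates, and donor strain stay open, since strain and transplant type change together. A rise in common with the coreceptor genes stays open too and was not tested.

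A set of 12 genes lay under 0.1 FPKM in every library of a group and over 1 FPKM in every library of the other. Of these, 100% were high in allo-HSCT (12 of 12, exact two-sided binomial p = 4.9e-04, with genes not independent). They included Trim12a, Trim5, H2-Q9, Apobec2, Gzmf and Ccl8. Trim12a had 1 read in the 3 syn-HSCT libraries together and 1190 in the allo-HSCT libraries. Reads of BALB/c alleles being lost against a C57BL/6 reference would give that direction, as would genes that BALB/c lacks. Induction in allogeneic T cells would give it too, above all for the granzyme gene Gzmf. Ccl8 rested on 32 reads over the 3 allo-HSCT libraries. Clustering at single strain loci cannot be told apart from chance placement, since 16.7% of the genes (the neighbours Trim12a and Trim5) lay within 500 kb of another, equal to the 95th percentile of 10000 draws of genes of like expression, and 12 genes are few.

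Allo-HSCT replicate 1 differed from replicates 2 and 3 with an SD of log2 differences of 0.257 and 0.236, where replicates 2 and 3 differed by 0.132 and syn-HSCT pairs by 0.134 to 0.17. Its deviation followed gene length (Spearman rho -0.33 over 5460 genes), with a median of 0.17 in the shortest of 5 equal groups of genes and -0.09 in the longest. Measured in the same way, rho was 0.333 for allo-HSCT replicate 2 and 0.179 for replicate 3, each against a mean that holds replicate 1. The trend therefore cannot be assigned to replicate 1 alone. Length may be part of why replicate 1 stood apart. It is not the whole reason, because the smaller SD was still 0.221 with the length trend removed, against 0.131 between the other pair. Other cells in its isolate cannot be excluded or shown, since the furthest median deviation of a list of another cell type was 0.37 (NK cell genes, some of which T cells share), between the bounds set for either answer. No biological explanation other than cell composition was tested for this library.

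The 6 samples allow only 10 splits into groups of 3, too few for a share under 0.05. The real split gave 5118 genes past the threshold, 1 of the 10 splits gave as many, and the highest of the others gave 0, in a table whose genes were chosen by the real split.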
